A study of Mus musculus with 12 samples.

How the data were processed

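RNA from sorted adipocyte precursor cells of mouse fat was sequenced as 12 libraries, 3 in each of 4 groups of depot (perigonadal, VWAT, or inguinal, SWAT) by diet (standard, SD, or high-fat, HFD). Per the labels, the mice were male C57Bl6/J of 6 to 8 weeks, the HFD held 60% lard and was fed for 3 days, SD samples are given as day 0, and each library was pooled from 3 mice. Per the labels' protocols, poly(A) RNA was made into libraries that mark the strand with dUTP and was read as 75 bp single ends. Per the submitters' processing notes, reads were aligned with TopHat and counted per gene with HTSeq on the mouse build mm9, with versions not given in the sources used here.

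The authors deposited 1 table of unnormalised read counts with 14398 genes and 3 further entries that name no gene. Those entries (reads in no gene, in more than 1 gene, or not uniquely aligned) held 3.53 to 5.57%, 1.71 to 1.95% and 14.98 to 20.81% of each library and were left out of library sizes and tests. The values were whole numbers, and every gene reached a count of at least 20 in some library. Reads from genes with near-identical copies, such as the haemoglobin genes, may fall among the reads not counted, so those genes are uncertain. So are overlapping and antisense genes, since the strand setting of the counting is not given in the sources used here. Symbols were used as in the table; 12881 are current symbols and 14169 current or older ones in the reference tables. No mm9 annotation was at hand, so no coordinates are given.

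The libraries held 17.6 M to 56.1 M gene counts (M, 1e6), and 378 genes had a count of 0 in at least 1 library. The 10 highest genes took 13.05 to 28.4% of the counts, TMM factors were 0.825 to 1.139, and mitochondrial genes took 1.11 to 2.15%. Genes were filtered with filterByExpr by group, which kept 14266 and removed 132. Differences were tested with edgeR's quasi-likelihood F test (version 4.0.16, robust, TMM, in R 4.3.3) in 1 fit of the 4 groups over 12 libraries, which shares the spread among them (prior degrees of freedom 5.01). The adjusted p is that of Benjamini and Hochberg over all genes tested, and a gene "passed", "rose" or "fell" when it was under 0.05. The contrasts were HFD against SD in each depot, the difference of these (interaction), and VWAT against SWAT on each diet, 5 in all. CPM are TMM-scaled counts per 1e6 counts, given as mean ± SD over 3 libraries. An exact test of 3 against 3 single values cannot go below a p of 0.1, so none was used for single genes.

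For genes with few counts in 1 group, ratios carry a 95% counting interval, and a group at 0 counts was set to a floor of 3 counts over the group.

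Gene lists, 37 in number, were fixed with the tests, the comparisons and the alternatives before the data were examined. They cover pathways, targets of transcription factors, precursor subsets, depot patterning and markers of other cell types. The 33 with at least 5 members past the filter were tested with limma camera (version 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within each comparison. camera compares a list with all other genes. With a correlation estimated for each list, none of the 12, 10 and 13 calls in the diet comparisons of VWAT and SWAT and in the interaction held, and 1 call held in each depot comparison. Where that value is the only alternative given for a list, it was the highest adjusted p over the list's alternatives. fry, which tests whether a list's genes move on balance one way and, in its mixed form, in either direction, called 13, 2, 0, 11 and 16 lists in VWAT, SWAT, interaction and the depots on SD and HFD, and 24, 14, 2, 27 and 28 in its mixed form. It compares a list with no other genes. Counts of members are given over all genes and "adjusted over the list alone", that is with Benjamini-Hochberg adjustment within the list.

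Named genes followed a rule: per comparison, the 8 largest changes in each direction among passing genes with a mean CPM of at least 5 in the higher group and no overlap between the groups' libraries (which chance gives 10% of genes), leaving out predicted models. Added were up to 4 members with the lowest adjusted p in each list, and Nr1h3, Nr1h2, Abca1, Abcg1, Srebf1, Scd1, Akt2, Mki67, Pparg and Cebpa. For the interaction, where none passed, the rule took the 5 lowest p. Some genes that met these rules are not reported here. Further members of lists with 5 or fewer changes, and those that moved against a list, were named after their values were seen.

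Alternatives were DESeq2 size factors or library size alone as scaling, no filter, DESeq2's Wald test (version 1.42.0), limma voom, only the 6 libraries compared, replicate number as a block, each library left out in turn, genes with a mean CPM of at least 5, fry and an estimated correlation. After the data were seen, 3 were added: leaving out VWAT_HFD replicate 3 and SWAT_HFD replicate 2 together, thinning all libraries to the smallest, and voom with sample weights.

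Whether replicate numbers pair libraries was checked from the correlation of same-number libraries after removing group means. Between VWAT_SD and SWAT_SD these were 0.18, 0.18 and 0.4, all over 0.1, so the numbers were taken to pair the depots on SD. This pairing is an assumption. The labels do not state it, 3 libraries in a group can hardly show it, and the main tests did not use it. Replicates 1 and 2 are hardly told apart there, since VWAT_SD 2 with SWAT_SD 1 had 0.16 and VWAT_SD 1 with SWAT_SD 2 had 0.09, and the other unlike numbers had -0.3 to -0.2. Between the depots on HFD they were -0.08, 0.18 and 0.07, and between diets -0.02, 0.03 and 0.07 in VWAT and 0.01, 0.12 and 0.13 in SWAT. No pairing was taken there, though 3 libraries can hardly show its lack between the depots on HFD either.

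The fit was tested on simulated data drawn for the 14266 genes from the real means and library sizes, with genes changed by 1.5, 2 or 4-fold. It recovered 46.3, 71.6 and 93.9% of these in VWAT, 38.8, 67.2 and 92.4% in SWAT, 9, 56.7 and 92.4% in the interaction, 40.3, 77.6 and 97% between depots on SD and 49.3, 70.1 and 92.4% on HFD. Of the unchanged genes 9, 13, 4, 7 and 7 were called in these comparisons. A shifted list was called in all 5 and 0 unshifted lists were. The simulated genes were drawn independently of each other, so this does not test lists whose genes move together.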

Results

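Messenger RNA was sequenced from adipocyte precursor cells, the fibroblast-like cells that give rise to fat cells. They were sorted by flow cytometry from the perigonadal (visceral, VWAT) and inguinal (subcutaneous, SWAT) fat of male C57Bl6/J mice. The gate kept cells without the blood marker CD45 or the endothelial marker CD31 that carried CD29, CD34 and Sca1, with or without CD24. The mice ate a standard diet (SD, which the labels give as day 0) or a high-fat diet (HFD) for 3 days, and each library was pooled from 3 mice. If the SD mice were collected before the HFD was given, the day of collection goes with the diet and cannot be told apart from it here. There were 4 groups, VWAT_SD, VWAT_HFD, SWAT_SD and SWAT_HFD, of 3 libraries each. The series title names dietary oleic acid and LXR alpha, a nuclear receptor for oxysterols encoded by Nr1h3, so the LXR genes and their targets were reported in each comparison.

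The gene counts per library were 52.1 M, 41.7 M and 47.6 M in VWAT_SD replicates 1 to 3 and 56.1 M, 49.1 M and 43.1 M in VWAT_HFD. They were 53.7 M, 47.7 M and 22.2 M in SWAT_SD and 17.6 M, 39.2 M and 52.6 M in SWAT_HFD. Between 14182 and 14365 genes had a count in a library. The first principal component held 63.6% of the variance and parted the depots, and the second held 15.8% and parted the diets. On the second, VWAT_HFD replicate 3 scored 2, the other VWAT_HFD libraries -37 and -46, and the VWAT_SD libraries 24.4 to 32.3.

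**Figure D1:**
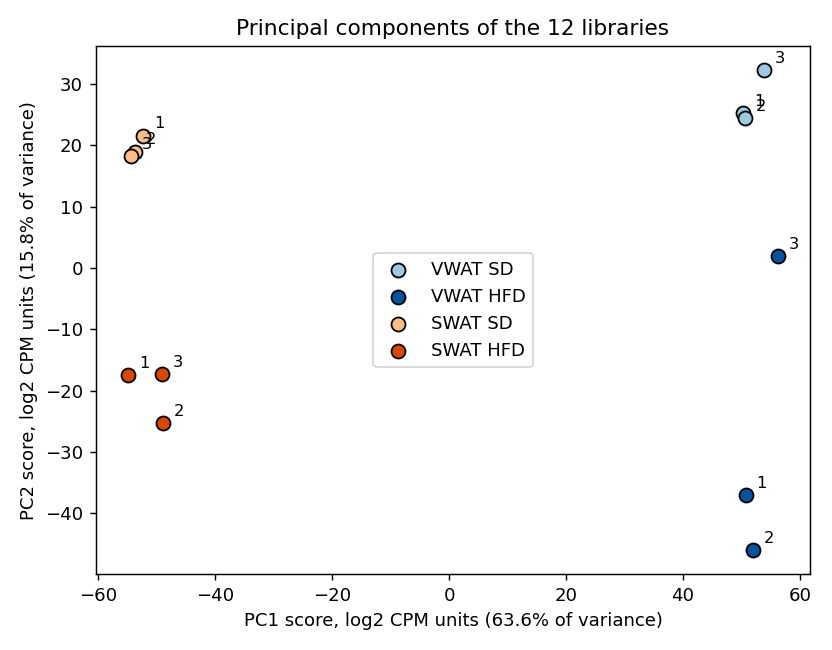
Scores of the 12 libraries on the first (63.6% of variance) and second (15.8%) principal components of log2 CPM, 1 point per library and 1 colour per group. VWAT_HFD replicate 3, at 2 on the second axis, lies between the VWAT_SD libraries (24.4 to 32.3) and the other VWAT_HFD libraries (-37 and -46).

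After 3 days of HFD, lists of mitosis, cholesterol synthesis and matrix genes were called up in VWAT precursors, and 10 of 22 genes of the chemokine and NF-kB list rose. Each of these list calls was lost with an estimated correlation (adjusted p = 0.352). Mki67, a marker of cycling cells, rose 8.15-fold, from 8.49 ± 2.55 to 69.1 ± 41.3 CPM (mean ± SD, n = 3; log2 change 3.03, SE 0.377, adjusted p = 0.000793). The sterol carrier Stard4 rose 2.91-fold, from 17.9 ± 3.77 to 51.9 ± 8.42 CPM (adjusted p = 0.000793). Inmt, an amine methyltransferase, fell 4.92-fold, from 730 ± 116 to 148 ± 67.7 CPM (adjusted p = 0.000793), and Pdk4, a kinase that spares glucose when fat is burned, fell 2.78-fold, from 46.5 ± 4.82 to 16.7 ± 2.74 CPM (adjusted p = 0.000956). The receptor tyrosine kinase gene Ret had the lowest adjusted p of this comparison (0.000241).

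The 8 largest rises that met the rule for named genes were Bub1, Depdc1a, Hmmr, Ube2c, Kif4, Kif23, Melk and Ncapg, all genes of mitosis or its regulation, at 10.6 to 12.8-fold. Bub1, a spindle checkpoint kinase, went from 0.530 ± 0.182 to 6.74 ± 3.91 CPM. The 8 largest falls were Inmt, Gsta3, Reep1, Igfbp3, Tgfbi, Cbx7, Gpnmb and Pdk4, at 2.78 to 4.92-fold. Among them the glutathione transferase Gsta3 fell from 20.6 ± 3.17 to 5.78 ± 2.99 CPM. The growth factor binding protein Igfbp3 fell from 49.1 ± 2.58 to 14.6 ± 1.00 CPM. Tgfbi, a matrix protein induced by TGF-beta, fell from 143 ± 12.5 to 45.3 ± 10.6 CPM.

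In all, 1232 of 14266 genes rose and 996 fell in VWAT, 421 and 171 of them by at least 2-fold. The total of 2228 was 1394, 1269 and 967 without VWAT_SD replicates 1, 2 and 3, and 1322, 757 and 4266 without VWAT_HFD replicates 1, 2 and 3. It was 1246 when only the 6 VWAT libraries were fitted. With library size as the only scaling the median log2 change of all genes was -0.126, against -0.017 with TMM, and the split was 799 up and 1822 down. No called list in any comparison turned its mean direction under that scaling, though that of fatty acid synthesis in VWAT was 0.012.

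All 30 mitosis genes rose in VWAT over all genes, and 30 adjusted over the list alone (mean log2 change 2.96, camera adjusted p = 8.63e-26, adjusted p = 0.352 with an estimated correlation). Top2a, the topoisomerase that untangles replicated chromosomes, rose 9.04-fold, from 8.13 ± 1.65 to 73.3 ± 42.9 CPM. Prc1, a spindle midzone protein, rose 7.84-fold and the kinesin Kif23 rose 11.1-fold. Of 33 DNA replication genes, 26 rose and none fell (31 adjusted over the list alone; mean 1.20, adjusted p = 1.27e-16, adjusted p = 0.352 with an estimated correlation). Uhrf1, which carries DNA methylation through replication, went from 5.64 to 18.4 CPM. The checkpoint mediator Clspn rose 5.68-fold and the transcription factor E2f8 rose 8.19-fold. The mitosis list stood at a mean log2 CPM of 2.46 in VWAT_HFD replicate 3, against 3.91 and 4.52 in the other VWAT_HFD libraries and 0.71 to 1.12 in VWAT_SD.

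Of 23 genes of cholesterol synthesis and uptake, 19 rose and none fell in VWAT (20 adjusted over the list alone). Their mean log2 change was 0.98 (adjusted p = 1.86e-15, adjusted p = 0.352 with an estimated correlation). Besides Stard4, the sterol sensor Insig1 rose 2.39-fold, from 75.5 ± 19.7 to 180 ± 36.1 CPM. The fatty acid synthesis list, 18 genes, moved less, with a mean of 0.12 (adjusted p = 0.0329, adjusted p = 0.352 with an estimated correlation). In it 5 genes rose and 1 fell, the same counts adjusted over the list alone. Scd2, a desaturase that makes oleate, rose 1.84-fold, from 124 ± 10.2 to 227 ± 3.44 CPM, and the synthase Fasn rose 1.62-fold, from 83.5 ± 7.72 to 135 ± 4.98 CPM. Mlxipl, the carbohydrate response factor ChREBP, fell 2.75-fold against the rest. The call of this list was lost without VWAT_SD replicate 1 (adjusted p = 0.0544) and without VWAT_HFD replicate 3 (0.196), within a range of 0.00469 to 0.352 over its alternatives.

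Of 13 targets of PPAR receptors that fatty acids induce, 2 rose and 6 fell (2 and 7 adjusted over the list alone; mean -0.15, adjusted p = 0.0215, adjusted p = 0.352 with an estimated correlation). Besides Pdk4, the lipase inhibitor Angptl4 fell 1.66-fold, from 291 to 175 CPM. The lipid-regulated factor Creb3l3 rose 3.91-fold, against the list. Without VWAT_HFD replicate 3 the list's adjusted p was 0.161 (range 0.00913 to 0.352). None of 18 beta-oxidation genes rose and 1, Acadm, fell, and the list was not called (adjusted p = 0.26) but passed as down without VWAT_HFD replicate 1 (0.0451).

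The LXR target list was not called in VWAT (adjusted p = 0.825), and its members went both ways. Of 16 genes, 5 rose and 2 fell (5 and 5 adjusted over the list alone). The mean log2 change was -0.03 and the median -0.11 while the test's direction was up. Scd2 and Fasn, which SREBP1 also drives, rose together with Arl4c, Rnf145 and Lpcat3. The phospholipid transfer protein Pltp fell 2.15-fold, from 61.0 ± 4.37 to 28.3 ± 4.73 CPM, and Smpdl3a fell 1.57-fold. fry's test in either direction gave an adjusted p of 2.78e-07 for this list, but it called 24 of 33 lists in VWAT. Nr1h3 itself was 43.8 ± 0.988 CPM on SD and 39.1 ± 6.45 on HFD (log2 change -0.17, adjusted p = 0.416). It passed under some alternative, within a range of 0.0107 to 0.885. Nr1h2, which encodes LXR beta, fell from 72.7 ± 4.82 to 56.9 ± 3.32 CPM (log2 change -0.35, SE 0.0792, adjusted p = 0.0106). That call was lost without VWAT_SD replicate 3 (adjusted p = 0.054), without VWAT_HFD replicate 2 (0.0637) and with only the 6 VWAT libraries (0.0533), within a range of 0.000265 to 0.0637.

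The cholesterol exporter Abca1, a classic LXR target, did not pass in VWAT, at 228 ± 34.9 CPM on SD and 152 ± 46.7 on HFD (log2 change -0.58, SE 0.216, adjusted p = 0.0871). It passed as lower without VWAT_HFD replicate 3 (log2 change -0.86, adjusted p = 0.00556), with DESeq2 (adjusted p = 0.0499) and with library size as the only scaling (0.0371), within a range of 0.000296 to 0.308. Abcg1, Srebf1, Scd1, Akt2, Pparg and Cebpa had log2 changes of -0.37, 0.18, -0.10, 0.03, -0.28 and -0.24 and did not pass (adjusted p 0.606, 0.203, 0.579, 0.84, 0.25 and 0.142). Pparg and Cebpa each passed under some alternative (ranges 0.0367 to 0.615 and 0.0346 to 0.392). None of the 23 insulin and PI3K-AKT components passed in either direction, over all genes or adjusted over the list alone (edgeR; list adjusted p = 0.654).

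Matrix genes rose as a group in VWAT, 25 of 30 with none falling (26 adjusted over the list alone; mean 0.79, adjusted p = 8.35e-16, adjusted p = 0.352 with an estimated correlation). The collagen genes Col5a3 and Col6a3 rose 1.91 and 2.01-fold, Col5a3 from 1182 ± 41.7 to 2261 ± 290 CPM. The chemokine and NF-kB list rose as well, 10 up and 1 down of 22 (13 and 2 adjusted over the list alone; mean 0.61, adjusted p = 0.00025, adjusted p = 0.352 with an estimated correlation). The monocyte attractants Ccl2 and Ccl7 rose 2.73 and 3.22-fold, Ccl2 from 660 ± 21.0 to 1803 ± 580 CPM, and the cytokine Lif rose 2.03-fold, whereas complement C3 fell. Of 20 genes of the unfolded protein and integrated stress response 4 rose (4 adjusted over the list alone; mean 0.45, adjusted p = 0.000787, adjusted p = 0.352 with an estimated correlation). Sesn2, a stress-induced inhibitor of mTORC1, rose 2.40-fold.

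Glucocorticoid response genes fell in VWAT, 5 of 14 with none rising (7 adjusted over the list alone; mean -0.37, adjusted p = 0.00861, adjusted p = 0.352 with an estimated correlation). Cebpd, an early factor of adipogenesis, fell 1.94-fold, from 1216 ± 67.2 to 629 ± 93.8 CPM. The Hox list fell, 5 of 26 with none rising (6 adjusted over the list alone; mean -0.41, adjusted p = 0.000185, adjusted p = 0.352 with an estimated correlation). Hoxc10, a posterior patterning gene, fell 1.83-fold but did not pass with limma voom or with only the 6 VWAT libraries. The visceral patterning list fell with a mean of -0.40, and in it Osr1 (1.62-fold) and Gata6 (1.32-fold) fell of 8 (2 adjusted over the list alone; adjusted p = 0.0412, adjusted p = 0.37 with an estimated correlation). That list was lost without VWAT_SD replicate 3 (adjusted p = 0.0748) and without VWAT_HFD replicate 1 (0.0714), within a range of 0.0159 to 0.37. The oxidative phosphorylation list of 32 genes was called up on a mean of 0.19 with 1 gene past the test, Cox5a, and 0 adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.896 with an estimated correlation, fry 0.45). It was lost without VWAT_SD replicates 1 and 2 (adjusted p 0.0685 and 0.053) and without VWAT_HFD replicate 1 (0.359), within a range of 3.66e-05 to 0.896.

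Other lists were not called in VWAT in the main fit. Of the adipocyte differentiation genes 2 fell and none rose, among them the hormone-sensitive lipase Lipe, 1.77-fold (list adjusted p = 0.211, and 0.023 without VWAT_HFD replicate 1). In the brown and beige list Ppargc1a fell and Dio2 rose (0.835). The DPP4 progenitor list had 1 up and 2 down, with Dact2 down 1.70-fold (0.969). The committed preadipocyte list had 2 up and 2 down, with a mean of -0.13 and a test direction of up (0.835), and the F3 regulatory stromal list 1 up and 1 down (0.892). The interferon list had 4 up and 1 down, Mx2 (0.0547). It was called up without VWAT_SD replicate 1 (0.0465), VWAT_HFD replicate 2 or 3 (0.0356 and 0.00703) or SWAT_HFD replicate 1 (0.0422), within a range of 0.00703 to 0.779. In ribosome biogenesis Srm and Odc1, both of polyamine synthesis, rose 1.64 and 1.59-fold (0.186). In the glycolysis list Hk2 rose 1.96-fold and Bnip3 fell 1.73-fold (0.626), and in the clock list Bhlhe40 rose 1.75-fold (0.752). Immediate early genes split 4 up, with Egr3 2.65-fold, and 4 down, with Fos and Egr1 (0.363).

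Markers of the sort gate and of other cell types were also read in VWAT. In the gate and mesenchymal list 4 of 10 rose, with Thy1 up 2.49-fold (list adjusted p = 0.191). The leukocyte list had a mean of -0.76 with Cd14 down (0.0608). It was called down without VWAT_SD replicate 1 (0.00908), VWAT_HFD replicate 1 or 2 (0.026 and 0.0205) or SWAT_HFD replicate 1 or 2 (0.0176 and 0.00376), within a range of 0.00376 to 0.896. The endothelial list had no gene past the test (0.937) and the mural list 3 up and 2 down (0.861). Mesothelial genes had 1 down, Rspo1 (0.566, and 0.0439 without VWAT_HFD replicate 2), skeletal muscle genes none (0.514), Schwann cell genes 1 down, Mbp, 2.19-fold (0.156), and the subcutaneous patterning list 3 down (0.211). The VWAT calls of Acadm, Cox5a, Ppargc1a, Dio2, Osr1, Gata6 and Rspo1 were each lost without VWAT_HFD replicate 2 (adjusted p 0.072 to 0.169) and without at least 1 other VWAT library.

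**Figure D2:**
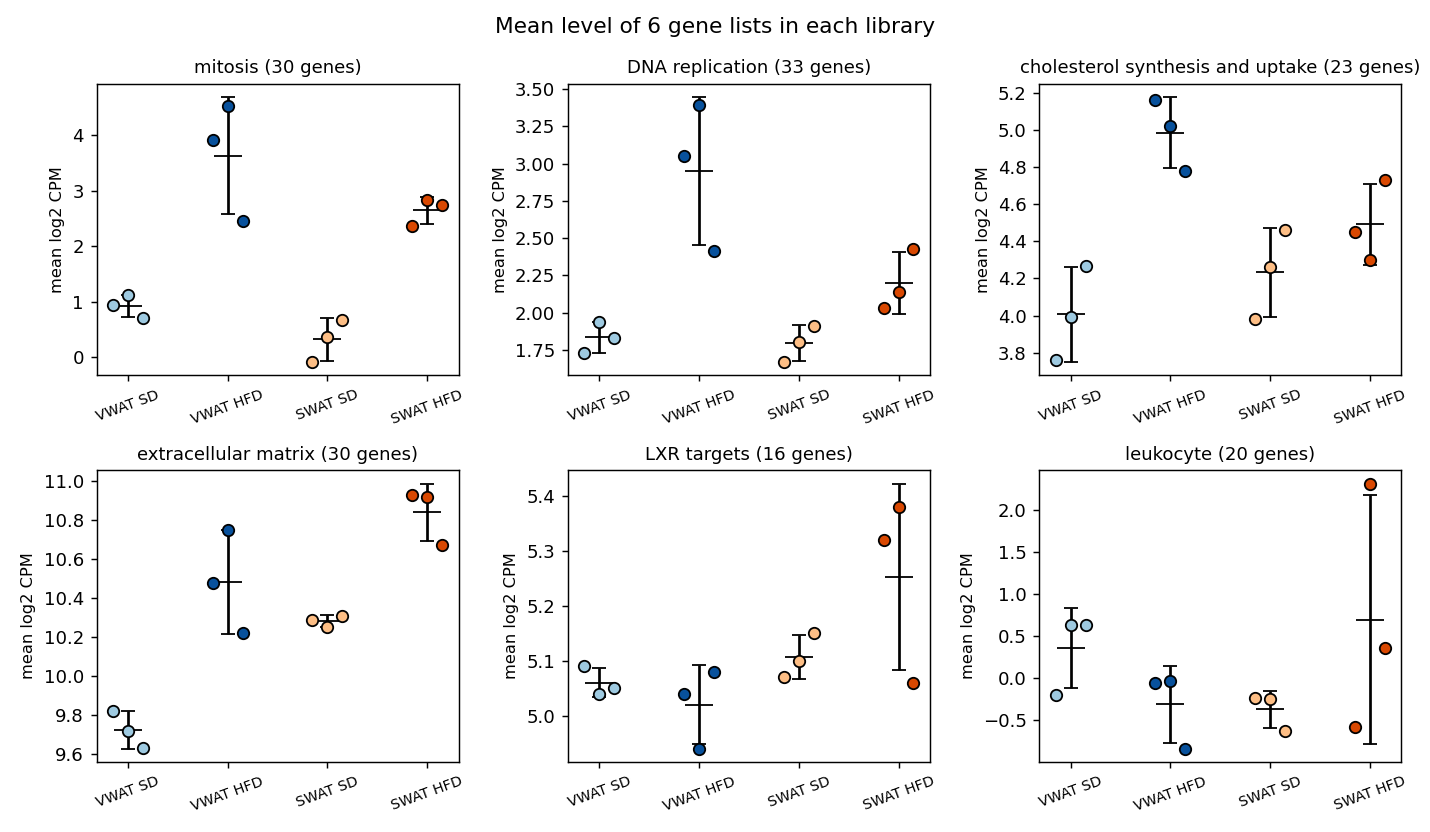
Mean log2 CPM of the members of 6 gene lists in each of the 12 libraries, with the mean and SD of each group of 3 as bars. The mitosis list stood at 2.46 to 4.52 in VWAT_HFD and 2.37 to 2.83 in SWAT_HFD, above all SD libraries (-0.08 to 1.12), and the leukocyte list was highest in SWAT_HFD replicate 2 (2.31).

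In SWAT precursors the same comparison, 3 days of HFD against SD, again raised cell division genes and the collagens Col3a1 and Col5a2, and it lowered the retinoid enzymes Cyp26b1 and Dhrs3. Mki67 rose 7.60-fold, from 4.14 ± 0.875 to 31.3 ± 5.25 CPM (log2 change 2.93, SE 0.399, adjusted p = 0.0189). Col3a1, a fibrillar collagen, rose 2.35-fold, from 41820 ± 1787 to 98210 ± 23410 CPM. Cyp26b1, which degrades retinoic acid, fell 5.09-fold, from 78.2 ± 32.3 to 15.6 ± 2.85 CPM (log2 change -2.35, SE 0.352, adjusted p = 0.0189), and Dhrs3, which reduces retinaldehyde, fell 1.76-fold, from 84.4 ± 10.8 to 48.2 ± 8.33 CPM. The chemokine Cxcl12 fell 1.68-fold, to 226 ± 9.64 CPM. Cyp26b1, Dhrs3 and Cxcl12 were also lower on HFD in VWAT, without overlap of libraries. Dhrs3 stood at 76.41 to 81.41 CPM in VWAT_SD and 33.13 to 37.53 in VWAT_HFD. For Cxcl12 these were 241.1 to 263.4 and 157.3 to 188, and for Cyp26b1, low in VWAT, 1.629 to 5.68 and 0.4615 to 0.9267.

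The 8 largest rises were Hmmr, Cenpf, Kif23, Cdca3, D17H6S56E-5, Mki67, Aspm and Cdk1, at 7.29 to 9.98-fold, and all but D17H6S56E-5 are known genes of the cell cycle. The 8 largest falls were Cyp26b1, Hrh2, Myoc, Adhfe1, St6galnac5, Rap1gap2, Dhrs3 and Cxcl12, at 1.68 to 5.09-fold.

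In all, 138 genes rose and 21 fell in SWAT, 93 and 9 of them by at least 2-fold, and 2120 genes had an unadjusted p under 0.05. The total of 159 was 0 without SWAT_SD replicate 1, 2 or 3 and 0 without SWAT_HFD replicate 2, so no SWAT call named here passed there. It was 50 and 98 without SWAT_HFD replicates 1 and 3. Because the spread was shared, it was 66, 80 and 79 without VWAT_SD replicates 1, 2 and 3 and 615 without VWAT_HFD replicate 3. DESeq2 called 536 genes and limma voom 12, and a fit of only the 6 SWAT libraries called 352. With library size as the only scaling the median of all genes was -0.177, against -0.001, and 162 of 263 calls were down. Mki67 had adjusted p of 0.108, 0.105 and 0.0586 without SWAT_SD replicates 1, 2 and 3 and 0.0803 without SWAT_HFD replicate 2, within a range of 1.18e-08 to 0.108.

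Mitosis genes rose in SWAT, 25 of 30 over all genes and 30 adjusted over the list alone (mean 2.41, adjusted p = 7.15e-35, adjusted p = 0.388 with an estimated correlation). Top2a rose 6.46-fold, from 5.43 to 34.3 CPM, and Prc1 5.60-fold. In the DNA replication list only E2f8 rose over all genes, and 8 adjusted over the list alone (mean 0.47, adjusted p = 0.00188, adjusted p = 0.922 with an estimated correlation); without SWAT_HFD replicate 3 the list's adjusted p was 0.205 (range 2.11e-05 to 0.922). Matrix genes had 2 up of 30 over all genes, Col3a1 and Col5a2, and 24 adjusted over the list alone (mean 0.57, adjusted p = 1.27e-15, adjusted p = 0.388 with an estimated correlation). Col5a1 had a log2 change of 0.79 and Col6a2 of 0.52 and did not pass (adjusted p 0.0505 and 0.0534). The transcripts of Col1a1, Col1a2 and Col3a1 made up 8.32 to 9.15% of gene counts in SWAT_SD and 12.4 to 19.45% in SWAT_HFD.

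The interferon list was called up in SWAT with 1 of 28 genes past the test, the guanylate-binding protein Gbp3 (11 adjusted over the list alone; mean 0.41, adjusted p = 2.1e-08, adjusted p = 0.442 with an estimated correlation, fry 0.0745). The cholesterol list was called with 1 of 23 up (1 adjusted over the list alone; mean 0.26, adjusted p = 0.0177, adjusted p = 0.922 with an estimated correlation). Without SWAT_SD replicate 1 and SWAT_HFD replicate 3 its adjusted p was 0.478 and 0.578 (range 0.000202 to 0.922). The chemokine list had 1 of 22 up, the adhesion molecule Vcam1 (5 up and 1 down adjusted over the list alone; mean 0.47, adjusted p = 0.0133, adjusted p = 0.672 with an estimated correlation). It was lost without SWAT_SD replicate 3 (0.0633) and without SWAT_HFD replicates 2 and 3 (0.0579 and 0.135), within a range of 0.000525 to 0.672. Glucocorticoid response genes had 1 of 14 down, Cebpd, 1.61-fold, from 994 ± 111 to 618 ± 61.5 CPM (1 adjusted over the list alone; mean -0.20, adjusted p = 0.0167, adjusted p = 0.672 with an estimated correlation). That list was lost without SWAT_SD replicate 2 (0.127) and without SWAT_HFD replicates 2 and 3 (0.0551 and 0.0634), within a range of 0.00143 to 0.672. The Hox list was called down with no gene past the edgeR test over all genes and 2 adjusted over the list alone (mean -0.25, adjusted p = 0.00188, adjusted p = 0.672 with an estimated correlation).

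Markers of other cell types moved beside these groups in SWAT. The leukocyte list had a mean of 1.73 with no gene past the edgeR test over all genes and 18 adjusted over the list alone (adjusted p = 0.000128, adjusted p = 0.779 with an estimated correlation). All 20 of its genes were highest in SWAT_HFD replicate 2, and without that library the mean was 0.45 and the adjusted p 0.197 (range 4.53e-12 to 0.779). The endothelial list had a mean of 0.82 with no gene past the test either way (adjusted p = 0.0101, adjusted p = 0.859 with an estimated correlation). It was lost without SWAT_SD replicate 3 (0.248) and without SWAT_HFD replicate 2 (0.178), within a range of 0.000121 to 0.859.

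LXR targets were not called in SWAT, with 1 of 16 up over all genes and 5 up and 1 down adjusted over the list alone (mean 0.17, adjusted p = 0.0849). The gene was Scd2, 1.40-fold, from 145 ± 11.5 to 203 ± 22.7 CPM (adjusted p = 0.0453). Without SWAT_HFD replicate 3 the list was called up (mean 0.26, adjusted p = 0.0244, range 0.0244 to 0.672). Nr1h3, Nr1h2, Abca1, Abcg1, Srebf1, Scd1, Akt2, Pparg and Cebpa had log2 changes of -0.02, -0.22, 0.19, -0.07, -0.04, -0.10, 0.03, -0.18 and -0.14 and did not pass (adjusted p 0.219 for Nr1h2 and 0.591 to 0.969 for the others). Fatty acid synthesis had Scd2 up and Mlxipl down 2.87-fold, with a mean of -0.10 and a test direction of up (adjusted p = 0.992). The stress response list had a mean of 0.11, a median of -0.02 and a test direction of down (0.992). The PPAR target, beta-oxidation, insulin and adipocyte differentiation lists were not called (0.317, 0.992, 0.992 and 0.903), nor were the other lists tested in SWAT (0.0644 to 0.992). Of those others the gate and mesenchymal list passed under some alternative (range 0.041 to 0.672).

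**Figure D3:**
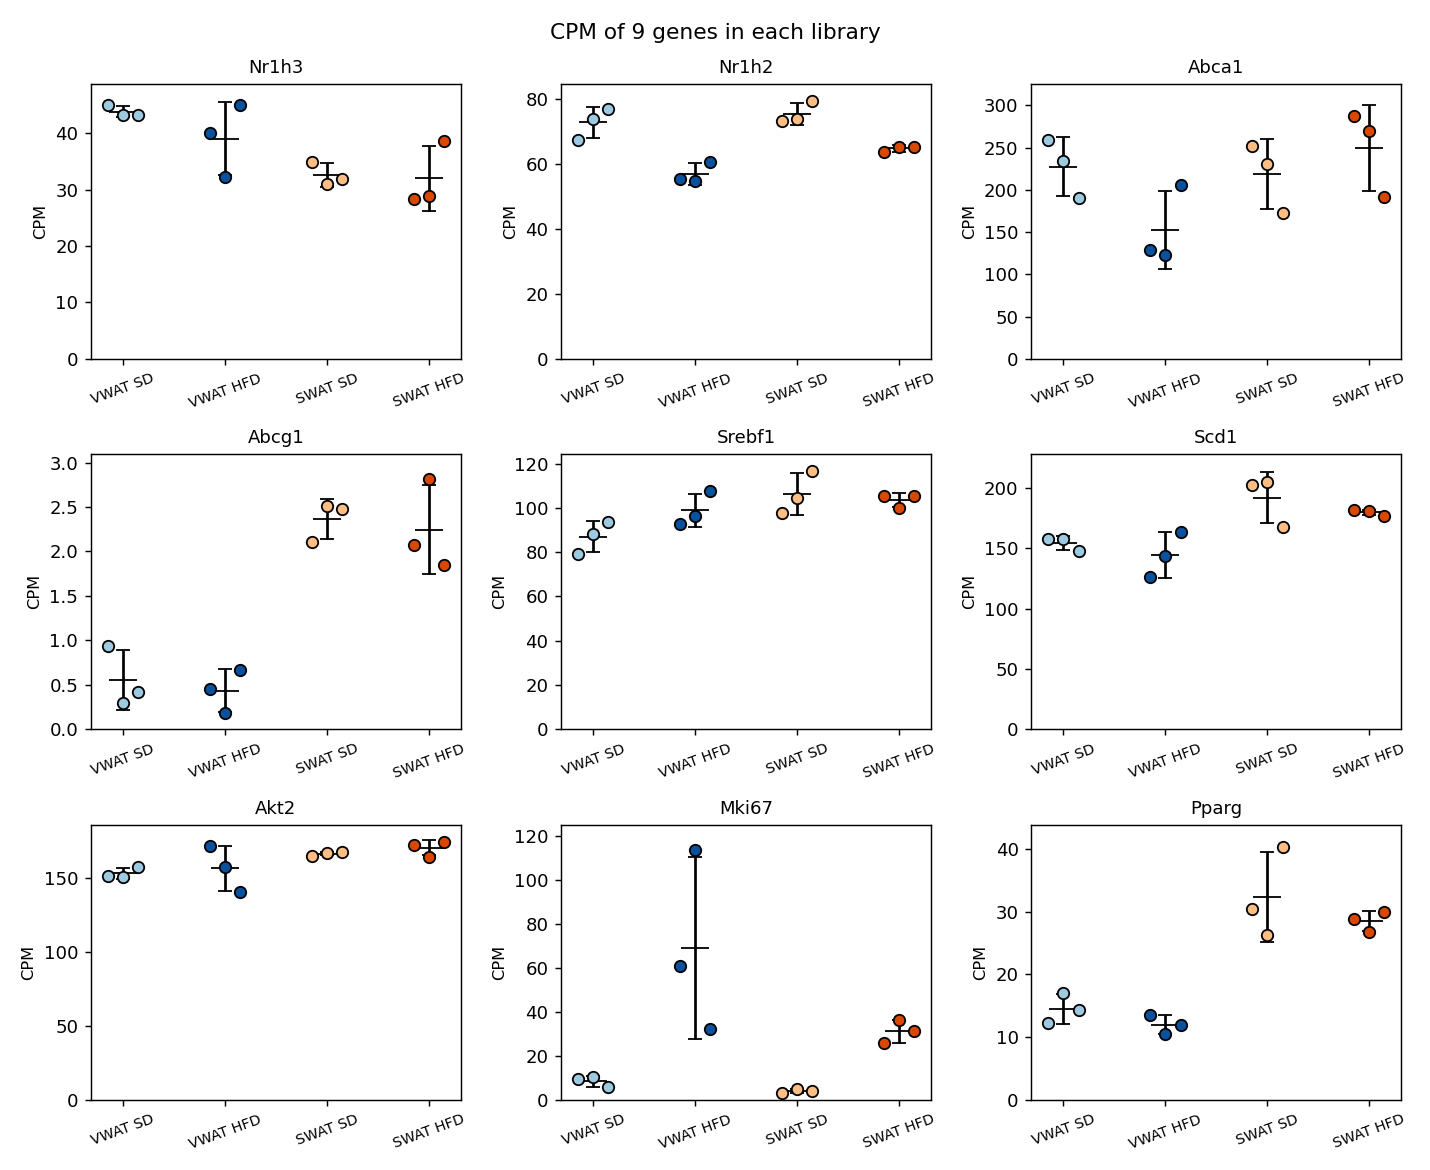
CPM of 9 genes in each of the 12 libraries, with the mean and SD of each group of 3 as bars and each axis starting at 0. Mki67 was higher on HFD in both depots, Nr1h2 was lower on HFD in VWAT, and Abcg1 and Pparg were lower in VWAT than in SWAT on either diet, while Nr1h3 was 43.8 ± 0.988 CPM in VWAT_SD and 39.1 ± 6.45 in VWAT_HFD.

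Whether the diet effect differed between the depots was tested as an interaction. No gene passed (0 of 14266, edgeR), although 1026 had an unadjusted p under 0.05; DESeq2 called 35 genes (24 higher and 11 lower in VWAT), limma voom 0 and limma voom with sample weights 622. Without VWAT_HFD replicate 3 edgeR called 135 genes, 71 higher and 64 lower. The lowest adjusted p was that of Hp, a haemoglobin scavenger (interaction log2 -1.82, SE 0.271, adjusted p = 0.205), which stood at 207 ± 26.7 CPM in VWAT_SD and 188 ± 37.7 in VWAT_HFD and rose in SWAT from 1.18 ± 0.156 to 3.59 ± 0.791 CPM (diet adjusted p = 0.0189). Among the next were Ret (1.14, SE 0.209), the imprinted gene Mest (1.16, SE 0.218) and the claudin Cldn10 (-1.33, SE 0.261), each at an adjusted p of 0.452. Hp passed with replicate number as a block (adjusted p = 0.0181, range 2.92e-06 to 0.78), but not with the block within diet (0.0966). Mki67, Nr1h3 and Abca1 had interaction log2 values of 0.10, -0.15 and -0.77 (adjusted p 0.987, 0.941 and 0.609). Abca1 passed under some alternative, with a lowest adjusted p of 0.0163.

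At the level of lists, 13 of 33 were called in the interaction by camera, but none with an estimated correlation or by fry's test in 1 direction. fry's test in either direction called fatty acid synthesis (adjusted p = 0.00972) and LXR targets (0.0464). Both lists hold Fasn, Scd1, Scd2 and Srebf1, so these calls are not independent. The cholesterol list had the lowest adjusted p, with 0 genes past the test over all genes and 14 adjusted over the list alone (mean 0.72, adjusted p = 1.53e-18, adjusted p = 0.538 with an estimated correlation). Tm7sf2 and Stard4 had interaction log2 values of 0.97 and 0.94, each not passing. DNA replication had a mean of 0.73 (adjusted p = 6.49e-17, adjusted p = 0.538 with an estimated correlation), the stress response list 0.34 (1.32e-05, 0.538 with an estimated correlation) and matrix genes 0.22 (0.000115, 0.69). The leukocyte list had -2.49 (1.3e-09, 0.538 with an estimated correlation; 17 genes adjusted over the list alone), and -1.20 without SWAT_HFD replicate 2 (3.86e-07, range 1.28e-20 to 0.538). The LXR target list was not called by camera (mean -0.19, adjusted p = 0.298). The mitosis list had a mean of 0.55 (0.0129, 0.743 with an estimated correlation) that was 0.07, with the test turned (adjusted p = 0.872, range 6.09e-14 to 0.872), without VWAT_HFD replicate 2.

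Across the 14266 genes the diet changes of the depots correlated with a Pearson r of 0.569 and a Spearman rho of 0.576; genes are not independent replicates. The slope of SWAT on VWAT was 0.482. Without SWAT_HFD replicate 3 r was 0.446, and over genes with a mean CPM of at least 5 it was 0.77. Of the 138 genes that rose in SWAT, 125 also rose in VWAT, against 11.9 if calls were independent, and of 21 that fell 17 also fell, against 1.5. None was called in opposite directions. Of the VWAT calls, 94.5% of those up and 90.9% of those down had the same sign in SWAT. The depots share no libraries, but their SD libraries were taken as paired, so differences between pools may enter both diet changes, which r and the numbers expected for independent calls leave out. A gene called in 1 depot alone is not thereby shown to differ between them.

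**Figure D4:**
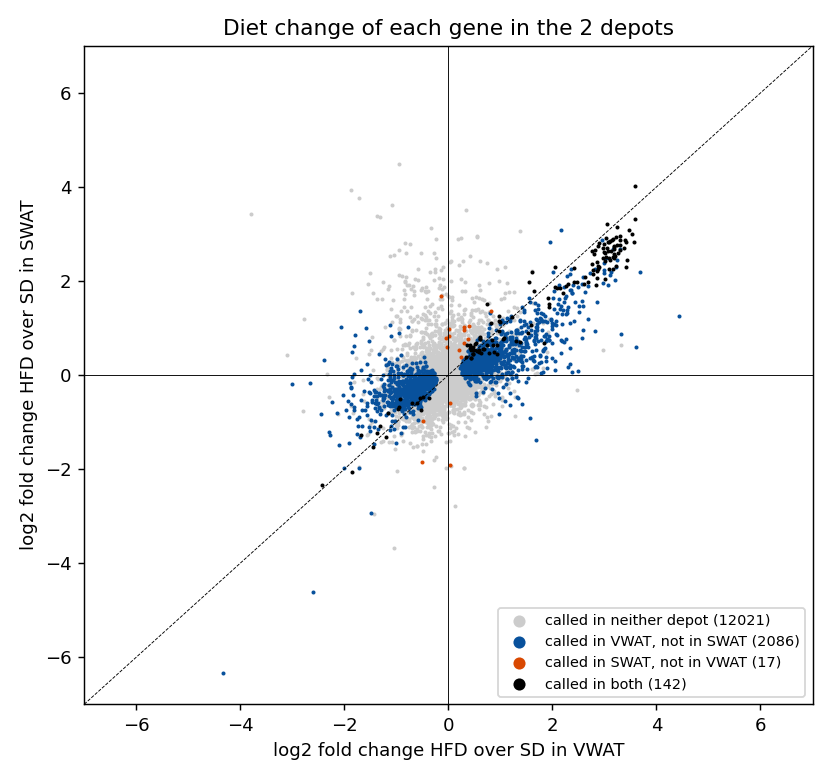
log2 fold change of HFD over SD in VWAT (x axis) and SWAT (y axis) for each of 14266 genes, coloured by the comparisons in which the gene passed, with the line of equal change dashed. Genes called in both depots (142) lie in the same direction in each, 2086 were called in VWAT only and 17 in SWAT only, and the Pearson r across genes is 0.569.

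The depots themselves, compared on SD, differed in developmental transcription factors, among other genes. Tcf21, a visceral mesenchyme factor, was 653-fold higher in VWAT, at 142.5 ± 2.32 against 0.207 CPM (adjusted p = 1.19e-10), and the mesothelial and visceral factor Wt1 236-fold higher, at 115 ± 15.4 against 0.435 CPM (adjusted p = 2.89e-10). Tbx15, a subcutaneous fat factor, was 214-fold lower in VWAT, at 0.531 against 115 ± 7.95 CPM (adjusted p = 1.64e-09), and Shox2 213-fold lower, at 0.202 against 43.2 ± 0.257 CPM. Pparg, the main regulator of fat cell formation, was lower in VWAT, at 14.5 against 32.4 CPM (log2 difference -1.15, adjusted p = 0.000108). The cholesterol exporter Abcg1 was lower as well (log2 difference -2.07, adjusted p = 0.00184).

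On SD, 1880 genes were higher and 1789 lower in VWAT, 917 and 763 of them by at least 2-fold. With library size as the only scaling the median of all genes was 0.236, against 0.018, and the split was 4279 higher and 1118 lower. Among the other genes of the largest differences were Mmd2, Gatm, Hp, Cadps and Col6a5 in VWAT. Hp stood at 207 ± 26.7 against 1.18 CPM and the collagen Col6a5 at 1519 ± 157 against 13.0. Mmd2 had 2 counts in all of SWAT_SD, a ratio of 1320 with a 95% counting interval of 366 to 10900. In SWAT they were Irx1, Lhx8, Tbx5, Il1r2 and Ces2b, with the decoy receptor Il1r2 at 340 ± 71.3 against 2.96 CPM, and Oprd1, which had 0 counts in VWAT_SD and was at least 380-fold lower there against a floor of 3 counts over the group. Intervals and floors cover counting error only.

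Of the SD lists, subcutaneous patterning was lower in VWAT in 8 of 9 genes (8 of 9 on HFD) and was the 1 list that held with an estimated correlation (adjusted p = 6.45e-09, and 0.0121 with an estimated correlation). Visceral patterning was higher in 6 of 8 (6.28e-05, 0.149 with an estimated correlation) and mesothelial genes in 7 of 10 with Krt19 lower (0.000236, 0.149 with an estimated correlation); Wt1 is in both lists. Interferon genes were lower in VWAT, 19 of 28 (mean -0.77, adjusted p = 1.37e-07, 0.258 with an estimated correlation), with Cxcl9 8.84-fold and Usp18 4.19-fold lower. DPP4 progenitor genes were lower in 8 of 12 with Cd55 higher (mean -1.04, adjusted p = 5.29e-05, 0.434 with an estimated correlation), among them Pi16 2.88-fold and Dpp4 2.50-fold, from 475 to 190 CPM. Matrix genes were lower in 18 of 30 with 2 higher (mean -0.56, adjusted p = 1.01e-05, 0.434 with an estimated correlation). The gelatinase Mmp2 was 2.96-fold lower, at 865 against 2556 CPM, and the thrombospondin Thbs1 4.50-fold higher, against the list.

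Brown and beige genes were lower in VWAT on SD in 4 of 8, with Tmem26 9.70-fold and Prdm16 2.50-fold lower (adjusted p = 0.00141, 0.161 with an estimated correlation). Schwann cell genes were lower in 5 of 7, with the myelin gene Mbp 4.87-fold lower (0.00427, 0.149 with an estimated correlation). Stress response genes were lower in 7 of 20, with Asns 1.81-fold lower (16 adjusted over the list alone; mean -0.38, adjusted p = 0.00141, 0.434 with an estimated correlation). Mitosis genes had 1 higher, Bub1b, 2.88-fold (mean 0.63, adjusted p = 0.0384, 0.982 with an estimated correlation). That list was lost without VWAT_SD replicates 1 and 2 (0.0634 and 0.152), SWAT_SD replicates 1 and 2 (0.204 and 0.0525) and SWAT_HFD replicate 3 (0.0576), within a range of 0.000454 to 0.982. LXR targets were not called, 3 higher and 6 lower of 16 (adjusted p = 0.484), with Mylip 2.05-fold lower and Apoc1 4.82-fold higher. Hox genes were not called (10 higher, 6 lower of 26; mean -0.20, median 0.26; adjusted p = 0.48).

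Of the fixed genes on SD, Nr1h3 was higher in VWAT (log2 difference 0.43, adjusted p = 0.0305), but not without any 1 of the 6 SD libraries (adjusted p 0.0538 to 0.106, range 0.00259 to 0.106). Cebpa was higher (0.34, adjusted p = 0.0357) and not without VWAT_SD replicates 2 and 3 (0.15 and 0.0597) or SWAT_SD replicates 1 and 2 (0.0561 and 0.162), within a range of 0.00237 to 0.162. Srebf1 was lower (-0.29, adjusted p = 0.041) and not without VWAT_SD replicates 1 and 2 (0.169 and 0.0881), SWAT_SD replicates 2 and 3 (0.0826 and 0.138) or VWAT_HFD replicate 2 (0.0539), within a range of 0.0101 to 0.638. Scd1 was lower (-0.32, adjusted p = 0.045), and not without VWAT_SD replicate 1, 2 or 3 (0.0928, 0.0898 and 0.136), SWAT_SD replicate 1 or 2 (0.108 and 0.159), VWAT_HFD replicate 2 (0.0594) or SWAT_HFD replicate 3 (0.0526), within a range of 0.00168 to 0.516. With replicate number as a block, Scd1 had an adjusted p of 0.0662 and Mki67 of 0.0214 (log2 difference 1.06) in place of 0.0716 (range of Mki67 0.0118 to 0.235). That block takes the SD pools of both depots as paired, but also joins libraries for which no pairing was taken. With the block within diet Cebpa did not pass. Nr1h2, Abca1 and Akt2 did not pass (0.693, 0.888 and 0.348).

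On HFD the depots kept part of these differences. Tcf21 was 342-fold higher in VWAT, at 111 ± 12.0 against 0.262 CPM (adjusted p = 2.38e-10), and Tbx15 194-fold lower, at 0.594 against 114 CPM. The cell division gene Mki67 was also higher in VWAT (log2 difference 1.14, adjusted p = 0.0288). In all, 1918 genes were higher and 1912 lower, 938 and 818 of them by at least 2-fold. Of the higher and lower genes, 1330 and 1348 were also called on SD, against 252.8 and 239.8 if calls were independent, and 0 in opposite directions (r of 0.89 across genes). With library size as the only scaling the median was 0.301, against 0.017, and the split 5830 higher and 1124 lower.

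Among the largest differences on HFD were Tcf21, Mmd2, Wt1, Cadps, Gatm, Ifltd1 and Epyc in VWAT, with the small proteoglycan Epyc 63.2-fold higher. In SWAT they were Oprd1, Lhx8, Shox2, Irx1, Tbx15, Tbx5, Dhrs9 and Irx5, with Shox2 315-fold and the retinol dehydrogenase Dhrs9 156-fold lower in VWAT. For genes with 2 or 3 counts in the lower group the ratios and 95% counting intervals were 333 (114 to 1610) for Mmd2, 382 (105 to 3160) for Oprd1 and 421 (116 to 3490) for Lhx8.

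Subcutaneous patterning again held with an estimated correlation on HFD (adjusted p = 1.71e-10, and 0.00775 with an estimated correlation). DNA replication genes were higher in 24 of 33 with 1 lower (mean 0.79, adjusted p = 2.88e-06, 0.747 with an estimated correlation), mitosis genes in 23 of 30 (1.18, 0.000191, 0.801 with an estimated correlation) and cholesterol genes in 10 of 23 (0.49, 0.000479, 0.747 with an estimated correlation), with Hsd17b7 2.30-fold higher. Interferon genes were lower in 24 of 28 (mean -0.93, adjusted p = 1.31e-10, 0.158 with an estimated correlation) and DPP4 progenitor genes in 9 of 12 (1.08e-05, 0.501 with an estimated correlation). Brown and beige genes (4 of 8 lower; 0.00118, 0.158 with an estimated correlation), Schwann cell genes (5 of 7 lower; 0.00377, 0.158), mesothelial genes (7 higher; 0.000316, 0.158) and visceral patterning (4 of 8 higher; 0.000879, 0.193) kept their SD direction, while the stress response list, lower on SD, was not called (mean -0.04, adjusted p = 0.654).

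Matrix genes on HFD were lower in 14 and higher in 4 of 30 (adjusted p = 0.00524, 0.747 with an estimated correlation). Leukocyte genes were lower in 8 of 20 (mean -1.64, adjusted p = 0.0121, 0.801 with an estimated correlation), and not without VWAT_HFD replicate 3 (0.0953) or SWAT_HFD replicate 2 (0.41), within a range of 2.58e-05 to 0.857. LXR targets were not called, 1 higher and 7 lower of 16 (adjusted p = 0.263). Pparg and Abcg1 were lower in VWAT (log2 differences -1.25 and -2.37, adjusted p 5.58e-05 and 0.000918). Abca1 was lower (-0.71, adjusted p = 0.0267), and not without VWAT_HFD replicates 1 and 2 (0.0956 and 0.114) or SWAT_HFD replicates 1 and 2 (0.0983 and 0.0827), within a range of 3.18e-05 to 0.114. The Mki67 call was lost without VWAT_HFD replicate 2 (0.188) and SWAT_HFD replicates 1, 2 and 3 (0.102, 0.0503 and 0.0716), within a range of 0.00035 to 0.188. Mki67 stood at 60.99, 113.8 and 32.37 CPM in VWAT_HFD replicates 1, 2 and 3, and at 25.95 to 36.45 in SWAT_HFD. Scd1 was lower (-0.32, adjusted p = 0.0442), and not without any single library other than VWAT_HFD replicate 3 and SWAT_SD replicates 1 and 3 (0.0531 to 0.152, range 0.00161 to 0.851). Nr1h3, Nr1h2, Srebf1, Akt2 and Cebpa did not pass (0.148, 0.106, 0.663, 0.334 and 0.135). Nr1h3, Nr1h2 and Cebpa each passed under some alternative (ranges 0.01 to 0.676, 0.00921 to 0.388 and 0.00334 to 0.422).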

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

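The tests on VWAT_HFD replicate 3 and on the leukocyte markers in SWAT were chosen only after those results were seen, and the others were first written before. The test of endothelial cells and the bound for a change in every HFD pool were changed again after a first version had counted against both explanations. The test of scaling first used means centred on all genes, which takes out any shift of all genes, and was replaced after its result was seen. The rule for the interaction count was changed as well, since a count of 0 cannot be tested by splits.

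The test of the difference between depots singled out 13 lists by camera, although no single gene passed and none of the lists held with an estimated correlation (adjusted p 0.271 to 0.743). Values are the mean log2 diet change in VWAT minus that in SWAT. They were 0.55 for mitosis, 0.734 for DNA replication, 0.717 for cholesterol synthesis and uptake, 0.22 for fatty acid synthesis and -0.123 for fatty acid responsive PPAR targets. They were 0.221 for the extracellular matrix, 0.141 for chemokines and NF-kB, -0.165 for interferon response, 0.343 for the stress response list, 0.169 for oxidative phosphorylation and 0.122 for ribosome biogenesis. The leukocyte list had -2.493 and the endothelial list -0.705. Those of cholesterol, DNA replication, stress response, matrix, leukocyte and fatty acid synthesis passed without any 1 library. Mitosis was lost without VWAT_SD replicate 3 (adjusted p = 0.0768), VWAT_HFD replicates 1 and 2 (0.131 and 0.872), SWAT_SD replicate 3 (0.257) and SWAT_HFD replicate 1 (0.194). Oxidative phosphorylation was lost without VWAT_HFD replicate 1 (0.327) and SWAT_SD replicate 3 (0.257), interferon without VWAT_HFD replicate 3 (0.515) and SWAT_HFD replicate 3 (0.152), and chemokines without SWAT_SD replicate 2 (0.059) and SWAT_HFD replicate 1 (0.253). Endothelial genes were lost without VWAT_SD replicates 1 and 2, VWAT_HFD replicate 3, SWAT_SD replicate 3 and SWAT_HFD replicates 2 and 3 (0.093, 0.169, 0.523, 0.307, 0.205 and 0.0616). Ribosome biogenesis was lost without VWAT_HFD replicate 3, SWAT_SD replicates 1 and 3 and SWAT_HFD replicates 1 and 2 (0.211, 0.0871, 0.0605, 0.243 and 0.213). PPAR targets were lost without VWAT_SD replicate 3, VWAT_HFD replicates 1 and 3, SWAT_SD replicates 1 and 2 and SWAT_HFD replicates 1 and 2 (0.117, 0.0515, 0.292, 0.105, 0.0627, 0.102 and 0.108).

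The larger change of the cholesterol and DNA replication lists in VWAT was weighed against technical causes. With all libraries thinned to the smallest they had 0.763 and 0.749. This cannot decide on unequal depth, since drawing counts at random hardly shifts a mean fold change. Under DESeq2 size factors they had 0.728 and 0.745 and under library size only 0.775 and 0.785. The median of all genes was -0.003, 0.006 and 0.062 under TMM, DESeq2 size factors and library size only. The choice among these scalings is therefore too small to account for the values. Differences between libraries unrelated to diet cannot be told apart from a depot difference: 29 and 56 of 200 splits of the diet labels within depots gave a mean as large, the highest others 1.35 and 1.523. What was written beforehand took such a share as showing that cause, but this was wrong, since splits that mirror the labels of 1 depot turn the difference of the diet effects into their sum (1.243 and 1.523 for the full mirror). A stronger response of the visceral depot, which the design names, may remain and was not tested apart from these.

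VWAT_HFD replicate 3 lay between the SD libraries and the other HFD libraries of its depot. By its mitosis genes a mislabelled SD library is argued against, because 30 of 30 stood above all VWAT_SD libraries in it. Genes of 1 list are not independent, so this counts for little more than 1 observation. Over all genes the library was nearer to SD. Its Spearman correlation was 0.993, 0.993 and 0.989 with VWAT_SD replicates 1, 2 and 3, and 0.986 and 0.987 with VWAT_HFD replicates 1 and 2. A uniform mixture with RNA of SD mice would place every list the same share of the way, but cholesterol genes stood at 51.3 to 72.9% and mitosis genes at 17 to 31.4%, ranges 19.9 points apart; that measure was changed once after a first result was seen. Fewer endothelial cells carrying the mitosis transcripts, although the gate excluded cells with CD31, cannot be told apart with 3 libraries: the mean log2 CPM was 2, 1.4 and -0.04 for the endothelial and 3.91, 4.52 and 2.46 for the mitosis list in VWAT_HFD replicates 1, 2 and 3, so both were lowest in replicate 3, the endothelial list by 1.74 and the mitosis list by 1.75 below the mean of the others, but replicates 1 and 2 stood in opposite order. The size of the endothelial drop depends on the measure. As summed CPM, the endothelial list was 252.4, 213.5 and 195.4 in VWAT_HFD replicates 1, 2 and 3. The mitosis list was 556.1, 869.5 and 217, a much larger drop to replicate 3. A weaker or slower response of that pool of mice may explain the position of the genes that lay between, and was not tested. Not all genes were intermediate. Inmt and Gsta3 lay between the diets in replicate 3. Ret stood at 70.87 CPM there, against 51.17 and 60.96 in replicates 1 and 2 and 15.23 to 20.87 in VWAT_SD. Igfbp3 stood at 14.56, against 15.57 and 13.56, and 46.82 to 51.9 in VWAT_SD. These genes were picked after their values were seen.

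The leukocyte list was higher on HFD in SWAT, with a mean of 1.729. A change of these genes was not seen in every high-fat diet pool. SWAT_HFD replicate 1 showed none, with 4 of 20 above all SWAT_SD libraries. Its mean log2 CPM of -0.59 lay within the -0.63 to -0.24 of SWAT_SD. Replicate 3 had 17 above and a mean of 0.36. Since 1 library decides little, whether the diet raises these genes in general cannot be told. All 20 were highest in SWAT_HFD replicate 2, which is consistent with leukocytes in that library, though not as the cause of the smaller rise in replicate 3: Ptprc, which encodes the CD45 that the gate excludes, stood at 6.93 CPM there and at most 0.536 in the other SWAT libraries, and Cd74 at 35.4 and at most 5.85. Without that library the mean was 0.445 (adjusted p = 0.197, range 4.53e-12 to 0.779) and the difference between depots -1.195 (adjusted p = 3.86e-07), against -2.493 with all libraries, a call lost with an estimated correlation (adjusted p = 0.538).

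Other splits of the libraries were counted for each count of genes. With 10 splits of 6 libraries the share cannot fall under 0.05. Every other split also mixes the groups, so a real difference enters the spread within groups. Calls near 0 in the other splits are therefore no reference for the size of the real count. The real VWAT split was the 1 with as many genes (2228, highest other 1), as were the real splits in SWAT (159, highest other 0), between depots on SD (3669, 0) and on HFD (3830, 0). On SD, where the numbers were taken to pair the depots, the 3 other splits that part every pair called 0 genes. For the interaction the count of 0 genes fixes the outcome, so its 100 of 100 splits decide nothing. The highest of them, 2745, exchanged the diets in SWAT only and so adds the diet effects of the depots, a structure of the samples.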

How the results depend on the processing

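Voom with sample weights, thinning, and leaving out VWAT_HFD replicate 3 and SWAT_HFD replicate 2 together were chosen only after the data were seen. DESeq2 size factors, no filter and thinning moved no count by over 1.5 times. Of 17371 alternatives of 778 gene results, 16208 kept direction and side of the threshold, 696 lost the call, 466 gained one and 1 turned. Of 2965 for 165 list results these were 2763, 148, 52 and 2. The turned values were Etfa between depots on HFD (0.017, library size only), the mitosis interaction (0.065 without VWAT_HFD replicate 2, with 0.92 without VWAT_HFD replicate 3 the other end of its range) and the endothelial interaction (0.063, both doubted libraries out).

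Leaving out 1 library at a time gave, as total, up and down, 757 to 4266 (493 to 2137, 264 to 2129) VWAT diet genes, 0 to 615 (0 to 451, 0 to 164) SWAT diet genes and 0 to 135 (0 to 71, 0 to 64) interaction genes. Depot genes were 2865 to 4411 (1356 to 2245, 1414 to 2166) on SD and 2852 to 4366 (1425 to 2233, 1427 to 2133) on HFD. Called lists were 11 to 15 in VWAT, 6 to 11 in SWAT, 9 to 14 in the interaction, 9 to 11 and 11 to 13 between depots on SD and HFD, and r was 0.446 to 0.594. Where 2 libraries of a group remained, the spread was shared with the other groups.

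Counts moved by over 1.5 times in these cases, and the cause was not tested except for the scaling shift. Library size only, which shifts the median of all genes, gave 799 up and 1822 down in VWAT, 263 with 162 down in SWAT, 4279 higher and 1118 lower between depots on SD, and 6954 (5830 and 1124) on HFD. Only 6 libraries, which give fewer degrees of freedom, gave 1246 (788 up, 458 down) in VWAT and 352 (272, 80) in SWAT. DESeq2 called 536 (414, 122) in SWAT and 35 (24, 11) in the interaction, with 3 to 1109 genes given no adjusted p, and voom 12 (6, 6) in SWAT. Sample weights gave 6302 (3101, 3201) in VWAT, 1581 (983, 598) in SWAT, 622 (290, 332) in the interaction, 5600 (2847, 2753) between depots on SD and 6045 (3116, 2929) on HFD; VWAT_HFD replicate 3 had the lowest weight, 0.211. With both doubted libraries out there were 4054 (2162, 1892) in VWAT, 249 with 49 down in SWAT, 46 (31, 15) in the interaction, and 8 interaction lists. An estimated correlation left 0, 0 and 0 lists in VWAT, SWAT and the interaction and 1 and 1 between depots, and fry 2 in SWAT and 0 in the interaction. Genes with a mean CPM of at least 5 gave an r of 0.77.

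With replicate number as a block, SWAT had 247 genes with 49 down and the interaction 1, lower in VWAT (Hp), and the interferon and leukocyte lists were called in VWAT (adjusted p 0.0498 and 0.0374). In the diet comparisons the libraries share only a number. The interaction joins depots taken as paired on SD with depots on HFD for which no pairing was taken. These are therefore not read as paired results, though a pairing on HFD cannot be excluded. With the block within diet the interaction had 0 genes, and Hp did not pass (adjusted p = 0.0966). Between depots on SD, where the numbers were taken to pair, the block changed no call of a count, a list or a fixed gene other than Scd1, Mki67 and, within diet, Cebpa (adjusted p = 0.055). The block within diet could not be fitted for the diet comparisons. For named genes with at most 3 counts in a group, ratios rested on a floor or carried wide counting intervals. The interaction recovered 9% of simulated 1.5-fold changes.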

Other observations

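Every test on gene lists in this part was written before its result was seen, but the lists of retinoic acid, AHR and NRF2, FOXO and amino acid genes were prompted by genes already seen, which were left out of them (Cyp26b1, Dhrs3, Gsta3, Inmt, Pdk4 and others).

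Collagen took a large share of the sorted cells' messages, higher in the HFD than in the SD libraries of each depot. The share itself was not tested. Col1a1, Col1a2 and Col3a1 together made up 3.06 to 3.5% of gene counts in VWAT_SD, 4.21, 6.94 and 8.35% in VWAT_HFD (replicates 3, 1 and 2), 8.32 to 9.15% in SWAT_SD and 12.4 to 19.45% in SWAT_HFD. Beside the collagens, genes that make and import amino acids rose in VWAT, 10 of 17 with none falling (adjusted p = 0.231 for the list with an estimated correlation).

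Among genes of the lowest interaction p, Mest stood at 18.8 and 20.1 CPM on SD and at 42.7 and 20.6 on HFD in VWAT and SWAT. Ret stood at 17.1 and 22.7 on SD and 61.0 and 36.6 on HFD, and rose in both depots (adjusted p 0.000241 and 0.0469). Neither gene passed between the depots on SD (adjusted p 0.722 and 0.062) or in the interaction (0.452 each).

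Lists with fewer than 5 members past the filter were not tested. These were lymphocyte (3 of 13), epithelial (2 of 10), epididymis (2 of 11) and erythroid genes (4 of 8). The lymphocyte list had mean log2 CPM of -1.52 to -0.68 in 11 libraries and 1 in SWAT_HFD replicate 2.

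Amino acid supply may accompany the rise of matrix genes. Predicted to rise, genes of amino acid synthesis and import had a mean log2 change of 0.483 in VWAT (camera adjusted p = 5.12e-05 over 8 tests, adjusted p = 0.231 with an estimated correlation) and 0.288 in SWAT (0.00484, 0.231 with an estimated correlation), where 1 gene rose. By camera that went with the prediction in both depots, while fry gave an adjusted p of 0.00287 in VWAT and 0.0594 in SWAT. Asns of this list had been seen before in the stress response list, which was called up in VWAT. A rise there could thus be partly foreseen. Amino acid supply was not tested apart from a stress response.

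The other predictions, all of falls, were not decided. Retinoic acid targets had -0.337 in VWAT, 1 up and 5 down of 15 (camera adjusted p = 0.139, fry 0.00287), among them the receptors Rarg (-0.62) and Rarb (-0.69) down and Rara up (0.32), and -0.23 in SWAT (0.157). The list also holds the enzymes of retinoic acid synthesis Aldh1a1, Aldh1a2 and Aldh1a3, so its mean mixes synthesis with response. Of these Aldh1a3 is among the falls in VWAT (-0.61). Lower retinoic acid signalling may be behind the falls, but camera did not set the list apart. AHR and NRF2 targets, tested for loss of plant compounds of the standard diet, had -0.165 in VWAT (0.441) and -0.065 in SWAT (0.259). FOXO targets, tested for stronger insulin and AKT signalling, had -0.159 in VWAT, 5 of 20 down, among them Txnip (0.157), and -0.056 in SWAT (0.594).

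The correlation of the diet changes between depots was compared with other splits of the diet labels in each depot. On log2 CPM means r was 0.623, and 2 of 200 splits gave an r of that size or more with its sign ignored, the real split and the one that mirrors the labels of 1 depot, which only turns the sign of r. The splits treat the depots as independent, although the SD libraries were taken as paired and differences between pools may enter both diet changes, so no p is given.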
